A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

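The data are messenger RNA profiles of the budding yeast Saccharomyces cerevisiae in 14 libraries, 1 per sample. Wild-type BY4741 cells (3 samples per medium) and cells in which the FPT1 gene is replaced by a KanMX cassette (4 samples per medium) were grown to mid-log phase in the rich glucose medium YEPD, and a second set was moved to ethanol for 2 h at 30 °C. Per the labels' protocols, RNA was purified on columns, treated with DNase, made into stranded poly(A) libraries and read as 65-base single reads. Poly(A) libraries do not measure tRNAs, the main products of RNA polymerase III, so transcript levels of tRNA genes are not analysed here.

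The deposited FPKM values (fragments mapped to a gene, divided by its length and by the library's mapped total) were used as the authors made them, in 1 table with a column per sample. Per the submitters' processing notes, STAR 2.7.1a and the sacCer3 genome build were used. The tool that turned alignments into FPKM, its annotation, its use of strand and any filter are not given in the sources used here. The values are not whole numbers, total 1649740 to 2027950 per library, and include non-zero values as low as 3.09e-25, so they are neither counts nor TPM and no count model was used. Each column matched 1 sample by its label. Groups and replicate numbers were taken from the sample titles. The series text calls the replicates biological, but no label says that each came from a separate culture, so p-values measure the spread between these samples, which may be partly technical. In the deletion groups, replicates 1 to 3 carry the strain name NKI5633 and replicate 4 the name NKI5620.

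Depth is not given. In coding regions of at least 900 bases with very low values, FPKM steps that correspond to 1 to 3 reads gave an estimate of 6060000 to 12700000 reads per library, assuming an effective length 200 bases shorter than the coding region. This rests on 10 to 21 low genes per library, of which 58.8% to 94.1% fell within 0.15 of a whole multiple, so it ranks the libraries only roughly and whole reads were not recovered. A gene near 1 FPKM therefore rests on a handful of reads.

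The table holds 6664 genes, of which 178 are at 0 in every sample. Gene names and positions came from the RefSeq annotation of the S288C assembly R64, matched by systematic name. The deposited table gives no coordinates, so no position was converted from sacCer3. An entry was found for 5989 genes, and 675 reading frames had none. Genes with at least 1 FPKM in at least 3 of the 14 samples were tested (6267 genes, 534 of them without a row in the annotation), and 397 were not.

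Values were taken as log2(FPKM + 1). A fold change on this scale understates the change of genes with low values. A linear model with 1 mean per group was fitted over all 14 samples with limma 3.58.1 (R 4.3.3; empirical Bayes with a mean-variance trend), so that all groups share 1 estimate of the spread. There were 5 two-sided comparisons: the deletion against wild type in each medium, ethanol against glucose in each strain, and the difference of these responses. P-values were adjusted by Benjamini-Hochberg within each comparison over the genes tested, with a threshold of 0.05. Errors are SEs of the log2 change or SDs of the FPKM values over replicates. No second scaling between libraries was applied in these fits.

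Before the data were examined, 28 gene lists were fixed for RNA polymerases I and III, kinases and phosphatases that signal to RNA polymerase III, tRNA processing, tRNA synthetases, ribosomal proteins, ribosome biogenesis, the tricarboxylic acid cycle, the respiratory chain, mitochondrial ribosomes, 2-carbon metabolism, glycolysis, hexose transport, other sugar genes, peroxisomes, reserve carbohydrates, stress, amino acids, sulfur, phosphate, iron, histones, proteasome, mating-type genes, meiosis, the neighbours of FPT1 and the strain markers. The hexose transport list also holds glucose sensors and regulators, among them SNF3, RGT2, MTH1 and STD1. A further list was made by a rule fixed at the same time: coding genes within 1000 bases of 1 of the 275 annotated nuclear tRNA genes. Of these, 25 lists were tested together and 4 are given as values only. The tests were camera with a preset correlation between genes of 0.01, camera with an estimated correlation, and fry. Camera compares a list with the other genes. The fry p used here asks whether the genes of a list move, on balance, one way, and compares them with no other genes. For each list the score of a library is the mean log2(FPKM + 1) of its members, compared by an exact two-sided permutation test. With 3 samples against 4 there are 35 splits, and the smallest p this test can give is 0.0286. For the difference of responses, genotype was permuted within each medium (1225 regroupings).

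The genes named in the text were set by a rule fixed before the data were examined. It takes FPT1, its 5 neighbours, the 4 marker genes, MAF1, BRF1 and RPO31 always. For the deletion in each medium and for ethanol in wild type it takes the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 10 FPKM in the higher group and no overlap between groups. For the difference of responses it takes the 5 largest called in each direction. From each list described it takes up to 4 called members with large changes or, where none is called, up to 2 of the most abundant. Genes outside this rule are said to be chosen after their values were seen.

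The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 10 FPKM, median scaling, quantile normalization, a replicate block, strain NKI5633 alone, a fit of only the groups compared, robust estimation, sample weights, a minimum fold, and leaving out each library. Their effect is given with the results that depend on the processing. The calculations were tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. At 1, limma recovered 93% for the deletion in glucose, 84% for the deletion in ethanol, 83% and 91% for ethanol in wild type and deletion cells, and 79% for the difference of responses. At 0.5 it recovered 53%, 61%, 59%, 66% and 43%. The simulated noise was independent between genes, unlike that of these libraries. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.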

Results

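Messenger RNA was measured in wild-type yeast and in cells lacking FPT1, in glucose and after 2 h in ethanol, to ask how loss of FPT1 alters messenger RNA levels in either medium and in the shift between them. Fpt1 is known as a protein found at genes read by RNA polymerase III, the enzyme that makes tRNAs. BY4741 is a standard MATa laboratory strain. Cells that leave glucose for ethanol must switch from fermentation to respiration. There were 3 wild-type and 4 deletion samples per medium, each with a deposited FPKM value per gene. Libraries held an estimated 6060000 to 12700000 reads, the median FPKM per library lay between 49.7 and 66.7, and 326 to 530 genes were at 0.

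FPT1 (YKR011C, chromosome XI, 461635 to 462696 in R64, minus strand, coding length 1062 bases) was abundant in wild-type libraries and nearly absent from deletion libraries. In wild-type glucose libraries it stood at 52.4, 51.9 and 51.9 FPKM, and in wild-type ethanol libraries at 136, 150 and 158 FPKM. The 8 deletion libraries reached at most 0.412 FPKM, and 4 of them were listed at 0. The deleted strain markers LEU2, URA3 and MET17 were listed at 0 in all 14 libraries. HIS3, carried as a partial deletion in this strain background, read 51.0 to 104 FPKM in every library. The nearest tRNA gene lay 2965 bases from FPT1.

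**Figure D1:**
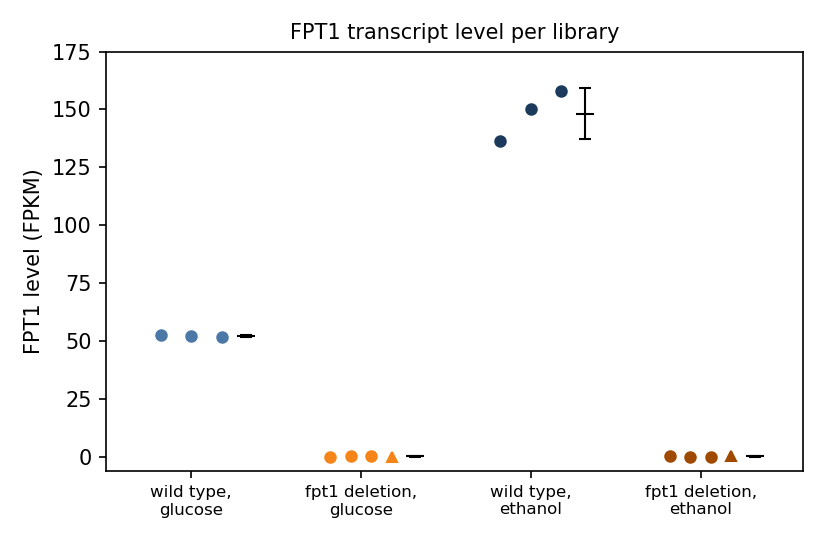
FPT1 level in FPKM (vertical axis) in each of the 14 libraries, by strain and medium. Points are libraries, triangles are strain NKI5620 and black bars are the mean ± SD, with wild-type libraries from 51.9 to 158 FPKM and deletion libraries at most at 0.412 FPKM.

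The medium separated the libraries far more than the genotype did. The first principal component of log2(FPKM + 1) held 82.0% of the variance and parted glucose from ethanol libraries. Deletion ethanol replicates 2 and 4 lay nearest to the glucose libraries among the ethanol libraries, at 35.3 and 31.8 on this component. The second held 5.48% and mixed the genotypes. Within groups, 31.0% of the remaining variance followed 1 component. Among the 200 genes that weigh most on it, 88% were reading frames absent from the annotation, against 8.52% of the genes tested. In glucose the NKI5620 library lay at a mean distance of 0.424 from the NKI5633 libraries, which lay 0.371 from each other. In ethanol these distances were 0.421 and 0.418.

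**Figure D2:**
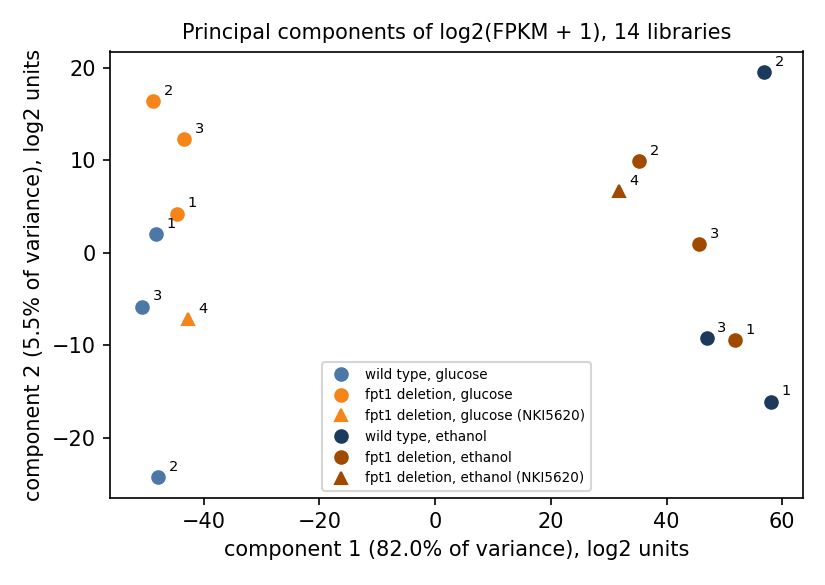
First and second principal components of log2(FPKM + 1), in log2 units, for the 14 libraries, numbered by replicate and coloured by strain and medium, with triangles for NKI5620. Glucose libraries lie on the left and ethanol libraries on the right of the first component (82.0% of variance), and the genotypes overlap on the second (5.48%).

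The first comparison asked what loss of FPT1 changes in growing cells in glucose. Besides FPT1 itself, 1 gene passed the test. SRL3 (chromosome XI, 611525 to 612265, plus strand), known as a dosage suppressor of a checkpoint kinase mutant, rose from 30.6 ± 0.372 FPKM in wild type (SD, n = 3) to 46.9 ± 2.42 in the deletion (SD, n = 4). Camera and fry called the hexose transport list, with its glucose sensors and regulators, and the other sugar genes higher in the deletion cells. No single member passed the threshold. Both calls were lost by camera, adjusted p = 0.25 with an estimated correlation, and by fry under quantile normalization. The transporter HXT2 stood at 237 ± 22.1 and 370 ± 61.3 FPKM in wild type and deletion, and the invertase SUC2 at 70.0 ± 6.61 and 89.6 ± 7.0.

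Of 6267 genes, limma called 2 for the deletion in glucose, 1 higher and 1 lower. An unadjusted p under 0.05 was found for 723, against 313 expected by chance. Genes move together in these libraries, which widens the spread of such a count, and the excess was not tested. FPT1 fell by 5.61 ± 0.15 on the log2 scale (adjusted p = 3.0e-11), a size set by the pseudocount, with -8.29 at pseudocount 0.1 and -3.49 at pseudocount 5. SRL3 rose by 0.60 ± 0.09 (adjusted p = 0.041), with all 4 deletion libraries above all 3 wild-type libraries. The median change over all genes was 0.08. Among genes chosen after their values were seen, EMI2, MPF1 and TMA10 came next, at 0.50, 0.53 and 0.82 (adjusted p = 0.053 for each). MTH1, a co-repressor of hexose transporter genes, differed by 0.71 and HAP4, the activating subunit of the respiratory regulator, by 0.49 (adjusted p = 0.073 for both). The SRL3 call was lost on leaving out any 1 of the 7 libraries, and it was kept in 4 of 17 alternative settings, 7 of which leave out a library, with adjusted p from 0.019 to 0.29. Not among the 17, robust estimation, sample weights and a fit of only the groups compared also kept it, and a minimum log2 change of 1 excludes it by its size.

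All 19 tested genes of the hexose transport list had estimates above 0 in deletion cells, with a median of 0.29. Not all of them encode transporters, since the list also holds glucose sensors and regulators such as MTH1. All 13 genes of galactose, sucrose and maltose use also had estimates above 0, with a median of 0.29. None passed over all genes, while 5 of 19 and 4 of 13 passed when adjusted over the list alone. Camera called both lists (adjusted p = 1.7e-04 and 1.6e-04), with adjusted p = 0.25 for both with an estimated correlation, and fry called both (adjusted p = 0.0024 and 0.0089). In the exact permutation test of the list scores, all 4 deletion libraries lay above all 3 wild-type libraries for both lists, p = 0.0286, the smallest this design allows, and 0.0794 after adjustment over 25 lists. Under quantile normalization fry called neither list, adjusted p = 0.51 and 0.67. MAL31, a maltose permease, differed by 0.59 (adjusted p = 0.14), and HXT3 by 0.36 (adjusted p = 0.33).

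Respiratory genes leaned the same way by less, and genes of protein synthesis leaned the other way. Median changes were 0.23 for 17 tricarboxylic acid cycle genes (16 estimates above 0), 0.17 for 38 respiratory chain genes, 0.13 for 70 mitochondrial ribosome genes and 0.22 for 20 reserve carbohydrate genes. They were -0.08 for 137 ribosomal protein genes, -0.03 for 135 ribosome biogenesis genes and -0.09 for the 20 tRNA synthetase genes, all 20 of them below 0. Camera called 13 of 25 lists, none of them with an estimated correlation (lowest adjusted p = 0.25 with an estimated correlation). Fry called only the hexose and sugar lists. Genes of tRNA processing and of amino acids had medians of 0.02 and 0.01 while camera pointed down (adjusted p = 0.0038 and 0.0021), adjusted p = 0.752 with an estimated correlation for both. No member of the 7 lists above passed over all genes. Adjusted over the list alone, 2 reserve carbohydrate genes passed and none of the other 6 lists had a member that did.

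The 21 genes of the RNA polymerase III machinery, the transcription system at which Fpt1 is found, showed a median change of 0.06, and camera did not call them (adjusted p = 0.63). No member passed, over all genes or adjusted over the list alone. MAF1, the repressor of RNA polymerase III, differed by 0.21 ± 0.12 (adjusted p = 0.52), RPO31, its largest subunit, by 0.09 (adjusted p = 0.75), and BRF1, an initiation factor subunit, by 0.07 (adjusted p = 0.76). The 376 coding genes near tRNA genes had a median of 0.06, below that of all genes, and camera did not call them (adjusted p = 0.52). Of the 5 neighbours of FPT1 none passed, with log2 changes of 0.07 for FOX2, 0.12 for TOF2, 0.02 for YKR012C, -0.12 for PRY2 and 0.08 for YPT52.

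The second comparison asked the same of cells 2 h after the move to ethanol. FPT1 fell by 7.0 ± 0.15 (adjusted p = 1.6e-12), with -9.44 at pseudocount 0.1 and -4.88 at pseudocount 5. MAG1, a DNA glycosylase that removes alkylated bases (chromosome V, 455146 to 456036, minus strand), fell from 157 ± 12.8 FPKM in wild type (SD, n = 3) to 105 ± 12.4 in the deletion (SD, n = 4). Camera called ribosome biogenesis genes higher in the deletion cells and reserve carbohydrate, stress and peroxisome genes lower, but fry called none of these lists, camera called none with an estimated correlation, and no member passed over all genes. Ribosome biogenesis scores were highest in deletion replicates 2 and 4, at 6.75 and 6.79, while deletion replicate 1 at 6.20 lay below wild-type replicate 3 at 6.37. NSR1, a nucleolar protein of ribosome biogenesis, stood at 277 ± 89.4 FPKM in wild type and 506 ± 136 in the deletion.

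Limma called 2 of 6267 genes, both lower, and 1510 genes had an unadjusted p under 0.05. The log2 change of MAG1 was -0.59 ± 0.09 (adjusted p = 0.042). Its call was kept in 7 of 17 alternative settings, 2 of the 7 that leave out a library among them, with adjusted p from 0.0051 to 0.28. Not among the 17, robust estimation and sample weights kept it, a fit of only the groups compared lost it, and a minimum log2 change of 1 excludes it by its size. Leaving out wild-type ethanol replicate 3 raised the count of called genes to 964 and leaving out deletion ethanol replicate 1 raised it to 912. Genes chosen after their values were seen included MIC19, of the mitochondrial inner membrane organising complex, at -0.55 (adjusted p = 0.067), and the tRNA methyltransferase genes TRM1 and GCD14 at 0.59 and 0.43 (adjusted p = 0.105 for both).

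Of 135 ribosome biogenesis genes, 134 had estimates above 0, with a median of 0.47. None passed over all genes and 116 passed when adjusted over the list alone. All 137 ribosomal protein genes had estimates above 0, with a median of 0.37, and none passed either way. Medians were 0.24 for RNA polymerase I genes (6 of 17 adjusted over the list alone), 0.16 for tRNA processing genes (19 of 52) and 0.17 for tRNA synthetases (4 of 20). On the lower side were stress genes at -0.36 (9 of 40 adjusted over the list alone), reserve carbohydrates at -0.31 (6 of 20), 2-carbon metabolism at -0.31 (0 of 27), the tricarboxylic acid cycle at -0.27 (1 of 17), peroxisomes at -0.25 (16 of 27), the respiratory chain at -0.20 (0 of 38), mitochondrial ribosomes at -0.15 (0 of 70) and the proteasome at -0.11 (0 of 33).

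Camera called 14 of 25 lists in this comparison, ribosome biogenesis with adjusted p = 1.6e-47, but none with an estimated correlation (lowest adjusted p = 0.45 with an estimated correlation). Fry called 0 of 25, with a lowest adjusted p of 0.084. The exact permutation test of the list scores gave adjusted p of at least 0.357. Wild-type and deletion libraries overlapped in every one of the 25 lists. The 21 RNA polymerase III genes had a median of 0.07 (camera adjusted p = 0.067, 1 member passing adjusted over the list alone). MAF1 differed by -0.27 (adjusted p = 0.20), RPO31 by 0.27 (adjusted p = 0.16) and BRF1 by -0.18 (adjusted p = 0.22).

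**Figure D3:**
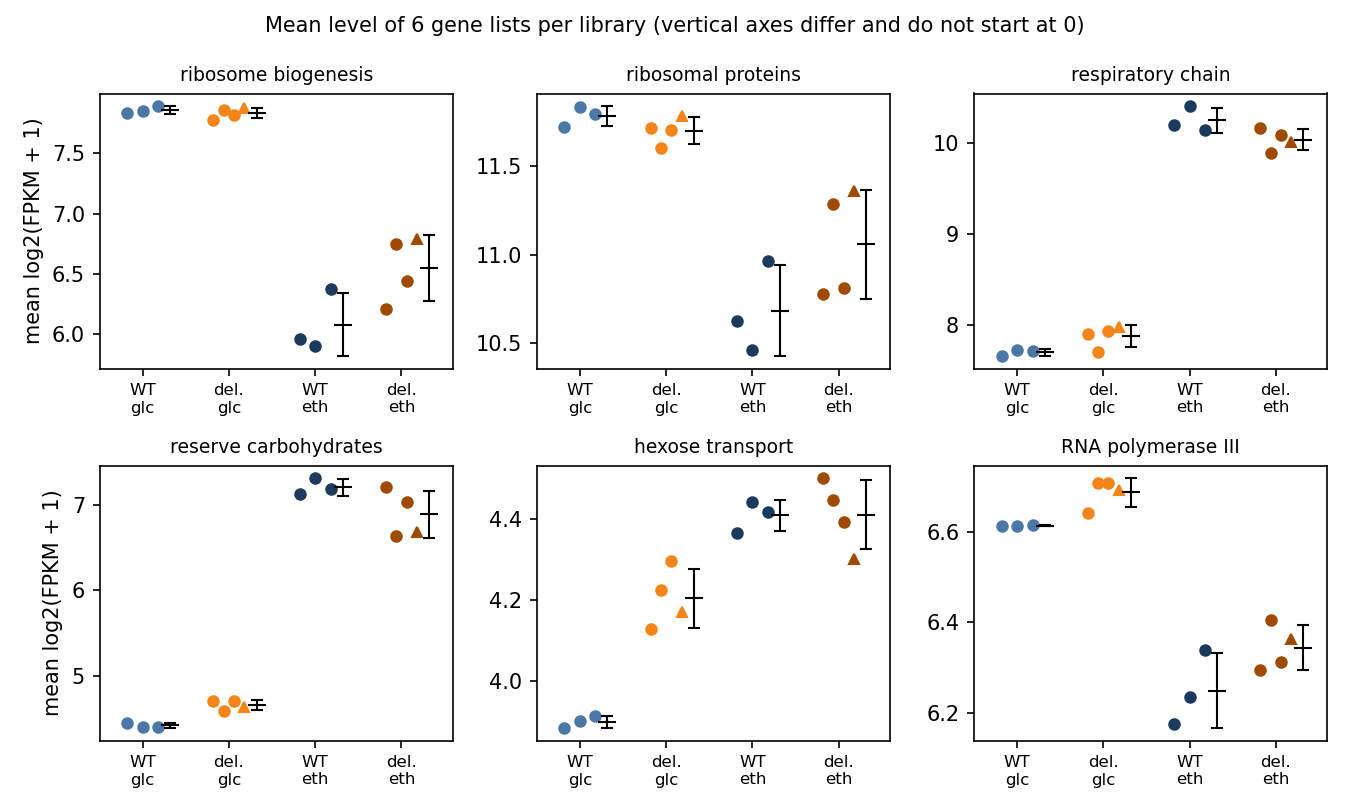
Mean log2(FPKM + 1) per library of 6 gene lists (vertical axes differ and do not start at 0), by strain (WT, wild type; del., FPT1 deletion) and medium (glc, glucose; eth, ethanol). Points are libraries, triangles are NKI5620 and bars are the mean ± SD. The hexose transport list also holds glucose sensors and regulators. In glucose it is higher in all 4 deletion libraries than in all 3 wild-type libraries (p = 0.0286, exact permutation test). Ribosome biogenesis in ethanol overlaps between the strains.

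The third comparison asked what 2 h in ethanol changes in wild-type cells. Genes for using non-fermentable carbon were among those that rose most. The lactate and pyruvate carrier JEN1 went from 1.99 ± 0.172 to 679 ± 171 FPKM (SD, n = 3 each), the ethanol-oxidising dehydrogenase ADH2 from 2.85 ± 0.717 to 672 ± 143, and the gluconeogenic fructose-1,6-bisphosphatase gene FBP1 from 1.71 ± 0.460 to 245 ± 68.5. The low-affinity glucose transporters HXT1 and HXT3 fell, HXT1 from 140 ± 11.3 to 0.670 ± 0.134 and HXT3 from 1034 ± 53.9 to 18.1 ± 1.89 FPKM. Genes for making ribosomes fell almost without exception.

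Limma called 4718 of 6267 genes, 3163 higher (67.0%) and 1555 lower, and 2100 of them changed by at least 1 on the log2 scale (1465 higher and 635 lower). The median change over all genes was 0.31. Median scaling sets that median to 0 and gave 2352 higher and 2355 lower (50.0% higher), and quantile normalization gave 2206 and 2503 (46.8% higher), so the excess of rises depends on the scaling. Medians of the lists are therefore also read against that of all genes, and the lists camera called kept the direction of their median under both scalings except the proteasome. Among lists only fry called, the kinases and phosphatases turned from up to down under both scalings, and glycolysis, then no longer called, under median scaling.

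The genes with the largest rises were RGI2 at 11.33 ± 0.41 (adjusted p = 5.2e-11), TMA10 at 8.51 ± 0.15, JEN1 at 7.80 ± 0.28, YFR052C-A at 7.74, HXK1 at 7.56, ADH2 at 7.44, SPG4 at 7.23, COX26 at 6.99, FBP1 at 6.47 and HXT7 at 6.29. RGI2 is known as a factor of respiratory growth and TMA10 as a ribosome-associated protein of stressed cells. YFR052C-A has no position in the annotation used, its systematic name places it beside HXK1, and whether its reads stem from HXK1 was not tested. HXT6 (5.47) and HXT7 are nearly identical in sequence, and their shares are uncertain. The largest falls were HXT1 at -6.40 ± 0.12 (adjusted p = 1.9e-13), HXT3 at -5.76 ± 0.12, PRM7 at -4.70, BSC1 at -4.62, RRT5 at -4.49, DBP2 at -4.39, YDR183C-A at -4.01, YMR230W-A at -3.83, RFU1 at -3.71 and SPO19 at -3.64. PRM7 and BSC1 lie next to each other on chromosome IV. FPT1 rose by 1.49 ± 0.16 (adjusted p = 8.3e-07) in wild type, and its neighbours FOX2, YPT52, PRY2 and TOF2 rose by 1.56, 1.08, 0.89 and 0.47, while YKR012C stood at 0.45 without passing.

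Among respiratory genes, 16 of 17 tricarboxylic acid cycle genes rose and 1 fell (median 2.46, or 2.15 above all genes), led by CIT3 at 4.98 and SDH1 at 4.17. All 38 respiratory chain genes rose (median 2.38), with the ATP synthase inhibitor INH1 at 5.32 and cytochrome c, CYC1, at 3.72, as did all 70 mitochondrial ribosome genes (median 1.45). Of 27 genes of 2-carbon metabolism 25 rose and 1 fell (median 3.59). Of 13 galactose, sucrose and maltose genes 11 rose, SUC2 by 4.75 to 1914 ± 274 FPKM. Peroxisome genes rose in 24 of 27 cases, with POX1, the first enzyme of fatty acid oxidation, at 4.57, reserve carbohydrate genes in 19 of 20, with the glycogen phosphorylase GPH1 at 6.27, and stress genes in 33 of 40, with HSP12 at 5.34. The counts adjusted over the list alone were the same for these 8 lists.

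Genes of protein synthesis fell. Of 135 ribosome biogenesis genes 132 fell and 1 rose (median -1.86, or -2.16 against all genes), led by the helicase genes DBP2 at -4.39 and DHR2 at -3.13. Of 137 ribosomal protein genes 132 fell and 2 rose (median -1.14), with RPL9A at -2.21 and RPL5 at -1.79. Many ribosomal protein genes have near-identical copies, and how reads were shared between copies is uncertain. All 20 tRNA synthetase genes fell (median -1.11), with the methionyl enzyme MES1 at -1.84. Of 52 tRNA processing genes 37 fell and 9 rose (10 rose adjusted over the list alone), with the pseudouridine synthase PUS1 at -2.42. RNA polymerase I genes fell in 13 of 17 cases and rose in 4, with its second-largest subunit RPA135 at -2.67. Amino acid genes went both ways, 37 falling and 12 rising of 58, from LEU9 at -3.14 to SNO1 at 4.58.

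The RNA polymerase III list split. Of 21 genes 11 fell and 7 rose, with a median of -0.30. The subunit genes RPC53, RPC82, RET1 and RPO31 fell by 1.65, 1.6, 1.38 and 1.23, RPO31 from 110 ± 7.11 to 46.6 ± 9.66 FPKM. The repressor gene MAF1 rose by 1.6 ± 0.13 (adjusted p = 6.2e-08), from 136 ± 5.19 to 415 ± 46.0 FPKM. BRF1 rose by 0.32 ± 0.09 (adjusted p = 0.0075), but this was -0.01 under median scaling and -0.02 under quantile normalization (adjusted p = 0.91 and 0.88), so it only followed the median of all genes. Of the 16 kinases and phosphatases that signal to RNA polymerase III, 8 rose and 4 fell. That is near the shares of all genes, 3163 and 1555 of 6267. Of 376 genes near tRNA genes 213 rose and 85 fell (median 0.44, camera adjusted p = 0.44).

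Smaller groups are set against all genes, of which 3163 of 6267 rose and 1555 fell. The shares of phosphate, hexose transport and meiosis genes that rose lay near that of all genes, and that of glycolysis genes was lower. Sulfur genes rose in 23 of 29 cases and fell in 4, led by MET28 at 3.89. Histone genes rose in 9 of 10, with the linker histone HHO1 at 1.52. Iron uptake genes rose in 17 of 27 and fell in 5, with the cell wall proteins FIT2 at 4.16 and FIT3 at 3.6. Phosphate genes rose in 9 of 18 and fell in 3, with GIT1 at 3.84 and PHO3 at -2.97. Proteasome genes rose in 27 of 33 (median 0.47), but the median was -0.01 under quantile normalization. Glycolysis genes rose in 8 and fell in 7 of 21, and hexose transport genes in 9 and 6 of 19. For hexose transport the median was 0.62 while camera pointed down (adjusted p = 0.82). Meiosis genes rose in 14 and fell in 5 of 25, with DMC1 at 2.94 and SPO19 at -3.64. Of 7 a-specific genes 2 rose and 2 fell (STE2 -1.26, AGA2 0.62), and of 4 alpha-specific genes 2 rose. STE3, the receptor of the opposite mating type, rose by 1.72 and reached 10 ± 2.08 FPKM. HIS3 fell by 0.46.

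Camera called 18 of 25 lists, none of them with an estimated correlation (adjusted p = 0.305 with an estimated correlation at the lowest, as for ribosome biogenesis and the respiratory chain, and adjusted p = 0.538 with an estimated correlation at the highest among called lists, for sulfur genes). Fry called 24, all but hexose transport.

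The fourth comparison asked the same of the deletion cells. They showed the same broad switch. JEN1 rose by 6.73 ± 0.24 and ADH2 by 6.54 ± 0.26, and HXT1 fell by 6.62 ± 0.10 and HXT3 by 6.01 ± 0.10. All 38 respiratory chain genes and all 70 mitochondrial ribosome genes rose (medians 2.06 and 1.16), and 132 of 135 ribosome biogenesis genes fell (median -1.37). MAF1 rose by 1.13 ± 0.11 (adjusted p = 5.8e-07), RPO31 fell by 1.05 ± 0.10 (adjusted p = 3.6e-07), and BRF1 did not pass at 0.06 (adjusted p = 0.50).

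Limma called 4672 genes, 2939 higher (62.9%) and 1733 lower, of which 1584 changed by at least 1 (1090 higher and 494 lower). The median of all genes was 0.19, and median scaling gave 2342 higher and 2376 lower (49.6% higher) and quantile normalization 2171 and 2565 (45.8%). Of 137 ribosomal protein genes 116 fell and 2 rose (119 fell adjusted over the list alone), with RPL5 at -1.20. All 20 tRNA synthetase genes fell (median -0.85). Of 17 tricarboxylic acid cycle genes 16 rose (CIT1 at 3.23), of 27 2-carbon genes 25 (median 2.97), of 20 reserve carbohydrate genes 19 (GPH1 at 5.37), of 40 stress genes 33 (HSP12 at 4.77), of 27 peroxisome genes 22 (POX1 at 3.59) and of 13 sugar genes 9 (SUC2 at 4.63). RNA polymerase III genes fell in 11 and rose in 4 of 21 cases. Adjusted over the list alone, 2 proteasome genes fell in place of 1 and 9 tRNA processing genes rose in place of 8. Camera called 18 lists, and fry 24, all but the kinases and phosphatases (adjusted p = 0.22), and camera called none with an estimated correlation (lowest adjusted p = 0.32 with an estimated correlation). The proteasome list (median 0.38) had a median of -0.06 under quantile normalization. For hexose transport the median was 0.54, while camera and fry pointed down.

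The last comparison tested whether the response to ethanol differs between the strains. Limma called 0 of 6267 genes, and 1603 had an unadjusted p under 0.05. Both strains called 2813 genes higher (1483 would be shared by independent lists) and 1448 lower (430), and none moved in opposite directions. Across genes, which are not independent replicates, the responses had a correlation of 0.959. The orthogonal slope of the deletion against wild type was 0.842, between 0.804 and 0.874 on leaving out any 1 library. Deletion ethanol replicates 2 and 4 both lay nearest to the glucose libraries, and the slope without the pair was not computed. Of 1820 genes whose mean response lay at least 1 from the median, 1581 (86.9%) had the smaller response in the deletion. This share was not tested on its own. MAF1 differed by -0.47 ± 0.17 (adjusted p = 0.15), RPO31 by 0.18 (adjusted p = 0.45) and BRF1 by -0.25 (adjusted p = 0.22). FPT1 differed by -1.39 (adjusted p = 0.079), which restates its deletion, and TMA10, chosen after its values were seen, by -1.21 (adjusted p = 0.088). Leaving out deletion ethanol replicate 1 raised the count to 844 genes, and leaving out wild-type ethanol replicate 3 raised it to 654.

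Most groups that rise in ethanol had lower estimates of the rise in the deletion cells, and tests called only some of them. Part of this came from higher scores of the deletion in glucose. Scores of deletion minus wild type in glucose and in ethanol were 0.30 and 0.0018 for hexose transport and 0.29 and -0.13 for galactose, sucrose and maltose genes. They were 0.20 and -0.24 for the tricarboxylic acid cycle, 0.24 and -0.32 for reserve carbohydrates and 0.13 and -0.33 for peroxisomes. In ethanol the strains overlapped in every list. The difference of responses was -0.63 for the median reserve carbohydrate gene, -0.43 for galactose, sucrose and maltose genes, -0.42 for the tricarboxylic acid cycle, -0.40 for peroxisomes and -0.39 for the respiratory chain, all called by fry and none by camera with an estimated correlation (lowest adjusted p = 0.42 with an estimated correlation). Deletion ethanol replicates 2 and 4 lay lowest in several of these lists: their tricarboxylic acid cycle scores were 8.31 and 8.35, against 8.65 in both other deletion libraries and 8.54 to 8.87 in wild type. The difference was -0.58 for 2-carbon metabolism and -0.52 for stress, which fry did not call (adjusted p = 0.071 and 0.061). It was -0.14 for sulfur, -0.06 for iron and 0.06 for phosphate genes (fry adjusted p = 0.54, 0.84 and 0.93), and for sulfur and iron camera pointed up. It was 0.49 for ribosome biogenesis and 0.45 for ribosomal proteins, called neither by fry (adjusted p = 0.072 and 0.093) nor by the exact permutation test (adjusted p = 0.121 for both). No member passed over all genes. Adjusted over the list alone, 15 of 20 reserve carbohydrate genes, 16 of 40 stress genes on the lower side, 15 of 17 tricarboxylic acid cycle genes and 0 of 135 ribosome biogenesis genes passed. CIT1, citrate synthase, differed by -0.68 ± 0.18 (adjusted p = 0.13) and GPH1 by -0.90 ± 0.29 (adjusted p = 0.14).

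Camera called 14 lists, with a lowest adjusted p of 0.42 with an estimated correlation. Fry called 8: the tricarboxylic acid cycle, the respiratory chain, mitochondrial ribosomes, hexose transport, the sugar genes, peroxisomes, reserve carbohydrates and genes near tRNA genes (adjusted p from 0.021 to 0.032). Of these, median scaling left 1 called and quantile normalization 0. The exact permutation test of the list scores gave an adjusted p of 0.0306 for 8 lists, 7 of them shared with fry and stress in place of hexose transport. The genes near tRNA genes had a median of -0.12, the same as all genes. For the RNA polymerase III genes the difference was 0.06 by the median (camera adjusted p = 0.22), and the exact test gave p = 0.784.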

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

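Chosen only after the result was seen were the tests of single libraries, of pairs of libraries and of sequencing depth below, the share of a difference kept under scaling and the counts of splits without FPT1. The 8 lists of carbon use and stress compared in glucose were picked after values were seen.

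Fry called the difference of the ethanol responses below 0 for 8 lists, while other lists with medians below 0, among them 2-carbon metabolism (-0.58) and stress (-0.52), were not called. The 8 were the tricarboxylic acid cycle (-0.42), the respiratory chain (-0.39), mitochondrial ribosomes (-0.27), hexose transport (-0.29), galactose, sucrose and maltose genes (-0.43), peroxisomes (-0.40), reserve carbohydrates (-0.63) and genes near tRNA genes (-0.12). Fry called 8 of these lists at first, 1 after median scaling and 0 after quantile normalization, but the mean score difference of -0.37 (mean SE 0.104) stayed at -0.25 (0.0881) and -0.24 (0.112), so the calls ended with smaller differences at a similar spread. Only the genes near tRNA genes went to 0.00 under both, and how much of the others scaling accounts for stays open, although the loss of calls alone met the bound set beforehand for scaling as the source. The level of absent reading frames as a covariate is excluded as the source, with a ratio of mean differences of 0.999. Leaving out any 1 library kept at least 0.845 of the mean difference, so no single library made most of it. Leaving out deletion ethanol replicates 2 and 4 together kept 0.697. Dropping ethanol libraries leaves the glucose part of each difference in place, so neither check measures the ethanol part alone. In ethanol, reserve carbohydrate scores were 6.64 and 6.68 in deletion replicates 2 and 4. They were 7.21 and 7.03 in replicates 1 and 3, and 7.12 to 7.31 in wild type. Sugar gene scores were 5.12 and 5.11, then 5.33 and 5.34, and 5.31 to 5.41 in wild type. The ethanol part of these lists thus lay mostly in replicates 2 and 4, while hexose transport did not split this way. Both checks compared sizes, not calls. Which libraries share a culture is not known.

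In glucose, 8 lists of carbon use and stress stood higher in the deletion. They were hexose transport, other sugars, reserve carbohydrates, the tricarboxylic acid cycle, stress, peroxisomes, 2-carbon metabolism and the respiratory chain. Hexose transport holds genes that rise and genes that fall in ethanol, so the lists are not all glucose-repressed. All 4 deletion libraries lay above all 3 wild-type libraries for 7 of the 8. That also held for RNA polymerase III, glycolysis, sulfur and genes near tRNA genes, and the mean of all tested genes was higher by 0.10. Scaling could account for part or most of this. Of the 8 lists, 5 kept this separation after median scaling and 2 after quantile normalization. The count of 2 met the bound set beforehand for scaling as the source. The mean score difference of 0.21 (mean SE 0.0356) became 0.14 (0.0368) and 0.09 (0.0586), so 65.1% and 41.6% of it were kept. The level of absent reading frames is excluded, with a ratio of 1.01.

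Reading frames absent from the annotation varied together between libraries of the same group. Sequencing depth stays open, with a correlation of 0.240 (95% limits -0.421 and 0.734; p = 0.474, permutation test) that too few libraries and a rough depth estimate leave undecided. Reads from the opposite strand could explain it. Among weak genes, with a mean under 10 FPKM, the median slope on the level of these frames was 0.691 for 26 that overlap a gene on the opposite strand. It was 0.0769 for 358 that overlap none, a difference of 0.614 (p = 1e-05, permutation test, the smallest that 100000 permutations can give). The test permuted genes, which share the same libraries, so its p does not measure the spread between libraries.

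Single libraries stood apart from the other 3 of their group for 19 of 420 values tested in the groups of 4, and chance flags about 1 in 20, or 21. The value is the gap to the nearest library over the range. In glucose it was 0.849 for the score of alpha-specific genes in deletion replicate 3. It was 0.851 for HYP2, 0.905 for VTC1, 0.970 for TPK3, 0.912 for RPN10 and 0.961 for RPS8B in deletion replicate 4. It was 0.940 for PRE1 in replicate 3, and 0.939 for INH1, 0.922 for DMC1 and 0.842 for RPA135 in replicate 2. In ethanol it was 0.955 for SUC2, 0.847 for INH1, 0.838 for SPL2 and 0.853 for SPO21 in deletion replicate 2. It was 0.944 for AGA2, 0.857 for SNZ1 and 0.934 for PRE8 in replicate 4, 0.865 for HSP10 in replicate 3 and 0.861 for DDR2 in replicate 1.

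Every split of the same libraries into groups of the same sizes was tested, except for the difference of the responses. There only 100 of the possible regroupings were tested, the real one included. For the deletion in glucose 1 of 35 splits called as many genes as the real 2 (highest other 1), but the deleted gene itself is 1 of the 2. Besides FPT1 the real split called 1 gene and the highest other 1, with 3 of 35 as large, so chance is not excluded for SRL3. In ethanol 5 of 35 did, with 2 real and 1198 in the highest other, so chance is not excluded. The split with 1198 differs from the real one only by an exchange of wild-type replicate 3 and deletion replicate 1. The large count thus points to a structure of the samples that follows genotype only in part. For ethanol in wild type there are only 10 splits, so the share of splits could not fall below 0.1 whatever the counts, and that share decides nothing. The counts themselves, 4718 real and 1 in the highest other, argue against chance. So does the first principal component (82.0% of variance), which parted all wild-type glucose from all wild-type ethanol libraries. In the deletion 1 of 35 splits called as many genes, with 4672 real and 0 in the highest other, so chance is excluded. For the difference of the responses all 100 regroupings tested did, with 0 real and 387 in the highest other among those tested. A real count of 0 fixes this outcome, so it says nothing on chance.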

How the results depend on the processing

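Added after the result was seen were the settings using only genes found in the reference, the covariate for the level of reading frames absent from it, and leaving out libraries for the list tests. Called genes for the deletion in glucose, 2 at first, were 1 with pseudocount 5, 1 with no filter, 5 with the stricter filter, 1 with median scaling, 1 with the replicate block, 1 with strain NKI5633 only, 8 with only the groups of the comparison in the fit, 603 with sample quality weights, 1 with a log2 change of at least 1 and 5 with reference genes only. Leaving out 1 library gave 1 to 2. In ethanol, also 2 at first, they were 4 with pseudocount 5, 1 with no filter, 1 with median scaling, 1 with quantile normalization, 1 with the replicate block, 1 with NKI5633 only, 1 with only the groups of the comparison, 308 with weights, 1 with a log2 change of at least 1 and 5 with reference genes only. Leaving out 1 library gave 1 to 964: 964 without wild-type ethanol replicate 3, 912 without deletion ethanol replicate 1, 2 without deletion replicate 3 and 1 without any other. For the ethanol response, a log2 change of at least 1 left 2100 genes of 4718 in wild type and 1584 of 4672 in the deletion, and the replicate block gave 4572 and 4505. Leaving out 1 library gave 4507 to 4660 and 4476 to 4647. For the difference of the responses, 0 at first, counts were 1 with pseudocount 5, 1 with no filter, 1 with NKI5633 only, 1036 with weights, 1 with reference genes only and 0 with the replicate block. Leaving out 1 library gave 0 to 844: 844 without deletion ethanol replicate 1, 654 without wild-type ethanol replicate 3, and 1 without wild-type glucose replicate 2 or deletion ethanol replicate 4. The cause was not tested. With weights, 16 of 35 splits of the ethanol libraries called at least as many genes as the real split, itself included, with 2421 in the highest other. Weighted counts in ethanol are therefore not specific to genotype. In glucose 2 of 35 did, itself included, with 744 in the highest other and a median of 0 in the others, so chance is not excluded there. BRF1 in wild type turned to -0.0107 with median scaling and -0.0153 with quantile normalization, and the median of the proteasome list under quantile normalization to -0.00669 in wild type and -0.0608 in the deletion. Of 2180 list values 2013 stayed the same, 93 became weaker, 32 stronger, 2 reversed and 40 that had not been called moved. Of 8601 values of named genes 8265 stayed the same, 50 became weaker, 122 stronger, 2 reversed and 162 moved. Residuals of libraries with the same replicate number in 2 groups correlated between -0.42 and 0.32 in 13 pairs, 3 of them over 0.1, and 4 of 13 were closest to their own number.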

Other observations

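The genes compared here were chosen only after the result was seen, and the test of chromosome ends was written down before it was run.

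In wild type, genes for the same step moved apart in ethanol. HXK1 and GLK1 rose by 7.56 and 4.75 while HXK2 rose by 0.56. PYK2 rose by 2.93 and CDC19 fell by 1.09. TDH1 rose by 4.17 and TDH2 fell by 0.81, with TDH3 at 0.09 (adjusted p = 0.404). ENO1 rose by 1.90 and ENO2 fell by 1.64. ACS1 rose by 5.16 with ACS2 at 0.04 (adjusted p = 0.499), and ADH2 by 7.44 with ADH1 at -0.06 (adjusted p = 0.594). Reads of TDH and ENO copies are hard to tell apart. The glucose sensors SNF3 and RGT2 moved apart, 1.96 and -0.86, as did the co-repressors MTH1 and STD1, 3.84 and -2.41. Of the ribosome biogenesis repressors, TOD6 fell by 3.17 and DOT6 stood at -0.03 (adjusted p = 0.736). In the deletion HXK2 rose by 0.58, CDC19 fell by 1.02, ACS1 rose by 4.25 and MTH1 by 3.25.

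Genes near chromosome ends could be released together in ethanol. Of 247 genes within 20 kb of an end 158 were tested, with medians of 0.67 in wild type and 0.50 in the deletion against 0.31 and 0.19 for all genes. Camera gave p = 0.0739 and 0.127, and p = 0.443 and 0.511 with an estimated correlation, so the hypothesis was not supported.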
